A study of Mus musculus with 69 samples.

How the data were processed

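RNA from the ventral striatum of 69 mice was sequenced, 35 of the HDID1 line, which was bred for high blood ethanol after drinking in the dark, and 34 of HSNpt, its heterogeneous control stock. Per the labels' protocols the mice had first taken a 4-day drinking test with a single bottle of 20% ethanol, given for 2 h on the early days and for 4 h on the last, from 3 h after lights off. Blood for the ethanol reading was drawn at the close of that last session, and the tissue was collected 3 weeks afterwards. The dissection was made by hand from a 2 mm coronal slice of thawed brain, and poly-A selected, stranded libraries were made and run 6 to a lane, per the labels' protocols. Lane assignments were not used here.

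The authors deposited whole-number read counts per gene and per exon, 1 column per mouse, with no normalization. Per the submitters' processing notes, CASAVA, FastQC, STAR, bedtools and edgeR were used with the mouse genome build mm10. Their versions, and whether counting took strand into account, are not given in the sources used here. Above the counts, the file headers give each mouse's sex, line, a lab number and a blood ethanol reading whose unit is not stated. The sex and line in the file headers were the same as in the labels for every library. There were 42279 genes in the gene table and 253821 exons in the other, and summed exon counts were equal to the gene count in every library for all 42252 genes found by name in both. The other 27 genes were not found by name in the exon table, where 25 names on 281 exons had turned into dates. No line of the gene table lacked a gene name, and 38602 of its names were found in GENCODE M21. Exons of 6197 genes overlap those of a gene on the opposite strand, and values of such genes are uncertain because strand in the counting is not known. All coordinates are those of the exon table on mm10.

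Counts per library summed to between 14077983 and 35257422, with a median of 17646316, and between 20373 and 24462 genes had at least 1 count. At the lowest total 1 count is worth 0.0710 CPM, and a count of 0 allows up to 3 counts, or 0.213 CPM, counting error only. No pair of libraries of the same group differed by so little that 1 library listed 2 times had to be considered, since the lowest chi-square per gene over all pairs was 5.99. The libraries formed 4 groups by line and sex. Replicate numbers follow the order of the samples, serve only as names and pair nothing.

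The choices in the next paragraphs, including the named genes, the gene lists and most alternatives, were made before the data were examined. Genes were filtered with filterByExpr on the 4 groups, which kept 16867, and scaled by TMM. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on 4 group means fitted to all 69 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The line effect is the mean of both HDID1 groups minus the mean of both HSNpt groups. The same fit gave the line effect within each sex, the line by sex interaction, and the male minus female difference over both lines and within each line. A standard error (SE) was taken as the size of the log2 fold change divided by the square root of F. Counts per gene are given as CPM, scaled to TMM library sizes, as mean and standard deviation over mice. Beside them stands the number of mice of the first group that lay above the median of the other.

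Exon usage was tested with edgeR's diffSpliceDGE on the 120938 exons that passed the filter in 12299 genes with at least 2 such exons, by Simes p per gene. Variability between mice was tested with limma 3.58.1 on absolute deviations of log2 CPM (prior count 2) from the group median. Gene lists were 18 sets of cell type markers and 25 sets of receptors, channels, pathways and sex-linked genes. They were tested with camera at a preset correlation of 0.01, adjusted over the 43 lists, then with an estimated correlation and with fry. Members were counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. Co-variation of the members of 41 lists across mice was compared between lines with 100000 permutations of line within sex. Neighbouring called genes of the same sign were counted against 100000 permutations, and windows of 20 tested genes against 10000.

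Genes are named by a rule. For the line effect these are the 10 with the largest rise and the 10 with the largest fall among genes that passed over both sexes and in each sex with a mean of at least 5 CPM. From each list up to 4 passing members with at least 1 CPM are named, those of smallest p, or the member of smallest p where none passed. For the interaction the 5 genes of smallest p are named, and for sex the X and Y lists and up to 5 autosomal genes in each direction. The 5 genes of smallest p are named for exon usage and, in each direction, for variability, along with the 5 windows holding the most called genes. Some genes that the rule takes are not reported here. Any other gene was chosen after its values were seen.

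Alternatives were RLE scaling, no filter or a stricter one (1 CPM in 17 libraries), DESeq2 1.42.0, voom with quality weights, sva 3.50.0 (its method gave 7 surrogate variables, and the limit of 5 was used), only the groups compared, line without sex, a test against a fold change of 1.2, and gene counts summed from exons. Others concerned the exon, variability, list and position tests. Alternatives added after the data were seen left out 3 libraries whose X and Y genes go against the label, 10 libraries that stand apart, or the 4 libraries with the highest totals, or added 6 marker scores, the 5' coverage balance or, with voom in place of edgeR's test, the lab number as a random block. A marker score is the mean over a list of log2 CPM relative to the mean library. A gene of a list whose score is a covariate thus has part of its own difference taken out by construction. The 5' balance compares counts in the upstream and downstream exons of 4781 genes with long transcripts. A library stands apart where its 5' balance or its spiny neuron score has a robust z under -3.5, a rule set after the principal components had been seen.

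The line, sex and exon tests were tried on simulated counts made from the real means and library sizes, with 200 changed genes. The variability test was tried on simulated log2 values, also with 200 changed genes. Genes were drawn independently of one another. The shares recovered and the other calls therefore leave out structure that the real libraries share across genes. For the line effect, 34% of genes changed by 1.2-fold were recovered, 90% at 1.5-fold, 94% at 2-fold and 98% at 4-fold, with 4 other genes called among 16783. For sex the shares were 34%, 92%, 94% and 98% in that order, with 7 other genes called among 16780. For variability they were 0%, 4%, 40% and 98% over 16867 genes, with 1 other call. For exon usage, run on 2193 genes, they were 0%, 36%, 100% and 100%, with 14 other calls. camera called the shifted list and 1 of 20 unshifted lists. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and R's data.table (1.17.8).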

Results

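Reads per gene and per exon were counted in the ventral striatum of HDID1 mice, a line bred for high blood ethanol after drinking in the dark, and of HSNpt mice, the heterogeneous stock that served as its control. There were 17 HDID1 females, 18 HDID1 males, 17 HSNpt females and 17 HSNpt males, 1 library per mouse. Counts per library summed to between 14772653 and 19680315 in HDID1 females and between 16636115 and 22150746 in HDID1 males. In HSNpt they lay between 14950883 and 22114477 in females and between 14077983 and 35257422 in males. Errors are standard deviations between mice unless called SE.

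The comparison of the lines asks which transcripts differ in this tissue between the selected line and its control stock. With a single selected line and a single stock, an effect of selection cannot be told apart from other differences between them. HDID1 mice had more reads of Pttg1, the inhibitor of sister chromatid separation known as securin, and of Thbs4, a secreted thrombospondin of the extracellular matrix. They had fewer reads of the class I histocompatibility gene H2-D1, the protease inhibitor Serpina3n, the endosome tether Eea1 and several clustered protocadherins. Of 14 genes shared by medium spiny neurons 5 fell, and of 9 marker genes of the hypothalamus 4 rose, though none of those 4 passed without 10 libraries that stand apart in 5' coverage or spiny neuron markers. Of 16867 genes tested, 1008 rose in HDID1 and 967 fell at an adjusted p under 0.05 by edgeR's quasi-likelihood test. Most of the 1975 differences were small, with 1621 under 1.5-fold and 110 over 2-fold.

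Gm1821, annotated as a transcribed processed pseudogene at chr14 46084126 to 46084815 on mm10, had the largest rise among the genes named by rule. It stood at 23.2 ± 14.7 CPM in 35 HDID1 mice and 1.48 ± 0.489 CPM in 34 HSNpt mice, a log2 fold change of 3.97 (SE 0.25, adjusted p = 1.25e-20), with 31 of 35 HDID1 mice above the HSNpt median. Its reads cannot be told from those of near-identical copies. Pttg1 at chr11 43420250 to 43426251 rose from 1.53 ± 1.27 to 9.38 ± 10.1 CPM (log2 fold change 2.60, SE 0.33, adjusted p = 1.99e-08), above the HSNpt median in 33 of 35. Thbs4 at chr13 92751590 to 92794818 rose from 4.03 ± 2.99 to 11.7 ± 8.07 CPM (log2 fold change 1.54, SE 0.25, adjusted p = 1.32e-05, 30 of 35). Sfi1, a centrin-binding gene with known copies and an overlap with Gm11399 on the opposite strand, rose from 34.6 ± 9.42 to 71.8 ± 34.5 CPM (log2 fold change 1.05, adjusted p = 4.34e-08, 33 of 35). Fcrls, a microglial receptor gene, rose from 5.55 ± 3.45 to 10.7 ± 4.25 CPM (log2 fold change 0.97, adjusted p = 1.07e-05) and was above the HSNpt median in all 35. The noncoding 4930412C18Rik rose by a log2 fold change of 1.36 (35 of 35), Lrrc48 by 0.99 (33), the aldo-keto reductase Akr1e1 by 0.97 (34), the noncoding 2810029C07Rik by 0.77 (33) and the signal recognition particle gene Srp9 by 0.67 (34). Srp9 overlaps a noncoding gene on the opposite strand.

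H2-D1 at chr17 35262730 to 35267499 fell from 27.8 ± 12.3 CPM in HSNpt to 9.35 ± 5.32 CPM in HDID1 (log2 fold change -1.57, SE 0.17, adjusted p = 2.24e-10), and 1 of 35 HDID1 mice was above the HSNpt median. Eea1 at chr10 95940663 to 96045518 fell from 31.2 ± 20.5 to 14.6 ± 4.25 CPM (log2 fold change -1.11, SE 0.18, adjusted p = 5.73e-06, 0 of 35 above). Serpina3n at chr12 104406729 to 104414329 fell from 54.4 ± 26.7 to 25.3 ± 9.83 CPM (log2 fold change -1.10, SE 0.17, adjusted p = 3.45e-06, 0 of 35). In the protocadherin clusters of chr18, Pcdhb6 had a log2 fold change of -1.08, Pcdhgb6 of -0.86 and Pcdhb7 of -0.77, and 0 of 35 HDID1 mice lay above the HSNpt median for any of them. Reads of these neighbouring copies and of the H2 genes may be split between them by the counting, which leaves their values uncertain. Variants of the founder strains against the reference could also shift counts without a shift in RNA, and this was not tested for single genes. The organic cation transporter Slc22a3 (log2 fold change -0.60, 2 of 35), the cytochrome Cyp4f14 (-0.57, 0 of 35), the membrane protein Prom1 (-0.57, 2 of 35) and the mitochondrial iron importer Slc25a37 (-0.56, 1 of 35) also fell. Prom1 overlaps Gm16401 on the opposite strand. All 20 of these genes passed in each sex, and each passed in 15 of 15 alternatives. With 6 marker scores as covariates the log2 fold changes of Pcdhb6 (-0.61), Pcdhb7 (-0.43), Slc22a3 (-0.35), Prom1 (-0.35) and Slc25a37 (-0.35) were over 1.5 times smaller.

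**Figure D1:**
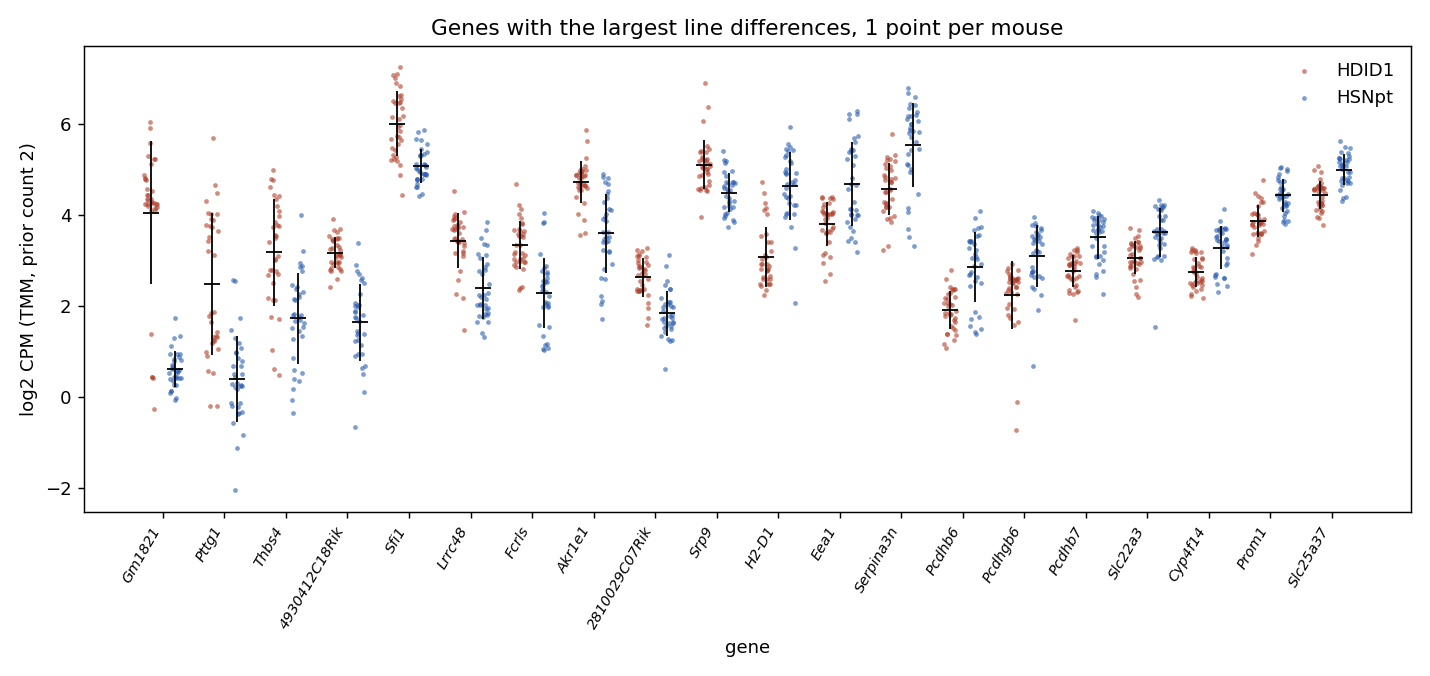
Log2 CPM of 20 genes, 1 point per mouse (35 HDID1, 34 HSNpt), with mean and SD as black marks. They had the largest line differences among genes that passed over both sexes and in each sex with a mean of at least 5 CPM. The first 10 genes lie higher in HDID1 and the other 10 lower, and the points of most genes overlap between the lines.

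Of 14 genes shared by both kinds of medium spiny neuron 5 fell and 0 rose in HDID1, 12 adjusted over the list alone, with a median log2 fold change of -0.39 (camera adjusted p = 7.92e-06, adjusted p = 0.706 with an estimated correlation). The phosphodiesterase Pde10a fell from 1164 ± 482 to 771 ± 394 CPM (log2 fold change -0.60, adjusted p = 0.0298, 6 of 35 above the HSNpt median). The phosphatase Ptpn5 (-0.40, 6 of 35), the transcription factor Foxp1 (-0.48, 7 of 35) and the adenylate cyclase Adcy5 were among the others that fell. Of the markers of D2 neurons 1 of 6 fell, 4 adjusted over the list alone, and camera called the list (median -0.38, adjusted p = 0.0255, adjusted p = 0.706 with an estimated correlation). That gene was the dopamine receptor Drd2, at 109 ± 45.8 CPM against 149 ± 52.6 (log2 fold change -0.45, adjusted p = 0.0469, 8 of 35). Of 9 D1 markers Sfxn1 rose (0.16) and Eya1 (-0.48) and Ebf1 (-0.32) fell, 4 adjusted over the list alone, with a camera adjusted p of 0.0843. The score of shared spiny neuron markers per library was -0.219 ± 0.768 in HDID1 and 0.225 ± 0.514 in HSNpt (permutation test, two-sided, p = 0.00503, adjusted p = 0.0232 over 47 measures).

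Among genes of synaptic and cyclic nucleotide signalling few members passed, and most of those fell. Among 16 phosphodiesterases of cyclic nucleotides 4 fell and 0 rose, 7 adjusted over the list alone (median -0.18, camera adjusted p = 1.52e-04, adjusted p = 0.706 with an estimated correlation), among them Pde8b (-0.34, 5 of 35 above) and Pde7b (-0.42, 6 of 35). In the postsynaptic list 3 of 23 fell and 0 rose, 8 adjusted over the list alone (median -0.18, camera adjusted p = 7.32e-05, adjusted p = 0.706 with an estimated correlation). These were the scaffold genes Homer1 (-0.63, adjusted p = 0.00232, 3 of 35), Dlg1 (-0.33, 2 of 35) and Dlgap3 (-0.30, 7 of 35). Calcium channel genes had 2 of 15 lower, Cacnb1 (-0.27) and Cacnb4 (-0.30), 4 adjusted over the list alone (camera adjusted p = 0.00709, adjusted p = 0.706 with an estimated correlation). Of 8 cannabinoid genes the receptor Cnr1 fell from 292 ± 92.5 to 184 ± 74.4 CPM (log2 fold change -0.67, adjusted p = 2.78e-04, 3 of 35 above), 4 adjusted over the list alone. Of 24 potassium channel genes 4 fell, among them Kcnab1 (-0.42) and Kcnq3 (-0.35), and Kcnj5 (0.55) rose, 8 adjusted over the list alone. In the presynaptic list Cplx2 (-0.27, 11 of 35) fell, 1 of 20 and 0 adjusted over the list alone. Camera called none of the last 3 lists, with adjusted p of 0.268, 0.0944 and 0.525. With 6 marker scores as covariates, spiny neurons among them, Pde8b (-0.18), Homer1 (-0.40), Dlg1 (-0.17) and Cnr1 (-0.33) still passed, each with a log2 fold change over 1.5 times smaller. No calcium channel, potassium channel or presynaptic gene did, and log2 fold changes were -0.0519 for Pde7b (adjusted p = 0.896), -0.0348 for Dlgap3 (0.858), -0.0360 for Kcnab1 (0.807) and -0.0911 for Cacnb1 (0.192).

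Of 15 genes of dopamine signalling 3 rose and 3 fell, 12 adjusted over the list alone, with a camera adjusted p of 0.928. Gnal (-0.34, 7 of 35 above), a G protein subunit of striatal dopamine receptors, fell with Drd2 and Adcy5, and the vesicular transporter Slc18a2 (0.53, 29 of 35) and the decarboxylase Ddc (0.46, 26 of 35) rose. The dopamine transporter Slc6a3 (2.24, adjusted p = 0.00199, 21 of 35) rested on 1 library, HDID1 female replicate 5, at 97.3 CPM when no other library was above 1.32. That library was also the highest for Slc18a2 and Ddc. Without the 10 libraries that stand apart Slc6a3 had a log2 fold change of 0.04 (adjusted p = 0.945), Slc18a2 of 0.23 (adjusted p = 0.150) and Ddc of 0.18 (adjusted p = 0.443). GABA-A subunits Gabra3 (0.22, 32 of 35) and Gabrg1 (0.28, 28 of 35) rose, 2 of 14 and 6 adjusted over the list alone. Grik1 (0.33, 29 of 35) rose among 17 ionotropic glutamate receptors, 1 adjusted over the list alone, and Grm3 (-0.28, 8 of 35) and Grm4 (-0.23, 6 of 35) fell among 7 metabotropic ones, 3 adjusted over the list alone. In the opioid system Oprl1 (0.30, 26 of 35) and Pnoc (0.61, 27 of 35), the nociceptin receptor and its precursor, rose, 2 of 8 and 3 adjusted over the list alone. Without the 10 libraries neither passed (0.20, adjusted p = 0.108, and 0.31, adjusted p = 0.352), and both lay below 0 with 6 marker scores as covariates (-0.0129 and -0.10). Camera adjusted p for these 4 lists were 0.525, 0.275, 0.376 and 0.792.

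Of 9 marker genes of the hypothalamus 4 rose, 7 adjusted over the list alone, with a median log2 fold change of 0.95 (camera adjusted p = 3.60e-04, adjusted p = 0.706 with an estimated correlation). These were Hcrt, the orexin precursor (2.84, adjusted p = 0.0094, 20 of 35 above the HSNpt median), Oxt, the oxytocin precursor (1.64, adjusted p = 0.0347, 29 of 35), Gal (0.97, 26 of 35) and Trh (0.86, 27 of 35). The general neuropeptide list had 4 of 16 higher and 0 lower, 5 adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.706 with an estimated correlation). Adcyap1 (0.83, 34 of 35) and Cartpt (0.58, 26 of 35) rose beside Gal and Trh. Markers of septum and thalamus (0 of 8, 1 adjusted over the list alone, median 0.57), choroid plexus (0 of 8 by either count, median 0.47) and ependymal cells (0 of 6 by either count, median 0.45) were also called by camera as lists, with adjusted p of 0.0496, 0.00896 and 0.0273, and adjusted p = 0.706 with an estimated correlation for each. Their members of smallest p were Slc17a6 (0.81, adjusted p = 0.0509, 26 of 35), Clic6 (0.26, adjusted p = 0.205, 27 of 35) and Enkur (0.49, adjusted p = 0.117, 25 of 35). Of 10 cortical markers (Rorb 0.28, adjusted p = 0.0574, 26 of 35) and 4 markers of the islands of Calleja (Plcb4 0.43, adjusted p = 0.0915, 26 of 35) 0 passed by either count, and camera adjusted p were 0.797 and 0.650. The choroid plexus score per library, HDID1 minus HSNpt, differed by 0.263 in females and 1.85 in males. In that order the differences were 0.244 and 0.957 for ependymal cells, 0.314 and 0.714 for septum and thalamus, and 0.417 and -0.493 for cortical markers. Whether these scores differ between the sexes was not tested.

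**Figure D2:**
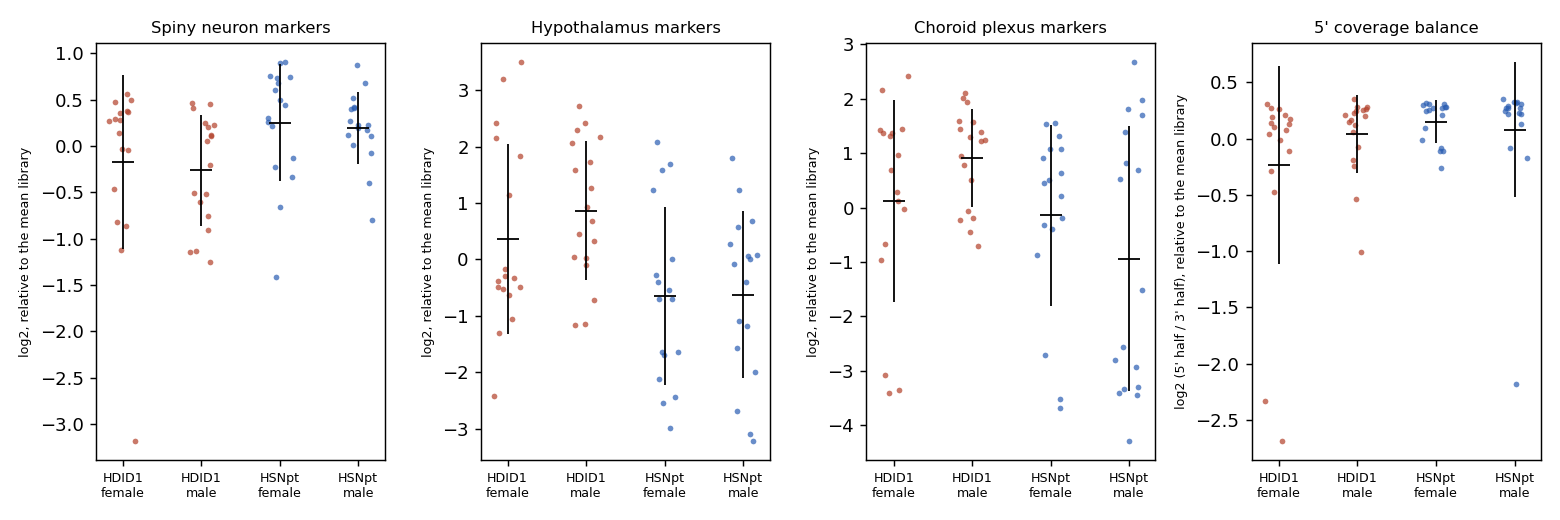
Scores of spiny neuron, hypothalamus and choroid plexus markers and the 5' coverage balance, in log2 relative to the mean library, 1 point per library in the 4 groups, with mean and SD as black marks. A few libraries lie far below the rest in spiny neuron markers, down to -3.18, and in 5' balance, down to -2.68.

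The hypothalamic score moved opposite to the spiny neuron score. It was 0.620 ± 1.47 in HDID1 and -0.638 ± 1.51 in HSNpt (permutation test, two-sided, p = 9e-04, adjusted p = 0.00859 over 47 measures). Of the 10 libraries that stand apart 8 of 35 were HDID1 and 2 of 34 HSNpt (Fisher's exact test, p = 0.0840). Their 5' balance lay between -2.68 and 0.309, against -0.259 to 0.353 in the other libraries, and their spiny neuron score between -3.18 and 0.361, against -1.14 to 0.903. Without them 1226 genes passed, 509 higher and 717 lower, and Hcrt (0.28, adjusted p = 0.872), Trh (0.38, adjusted p = 0.397), Gal (0.65, adjusted p = 0.181), Oxt (0.98, adjusted p = 0.264) and Pde10a (-0.41, adjusted p = 0.059) were among 38 of 121 named results that no longer passed. Beside genes given elsewhere with their values these were Drd2, Foxp1, Slc1a2, Gjb6, Slco1a4, Pecam1, Abcc9, Gabrg1, Grik1, Gnal, Adcyap1, Cartpt, Pde7b, Kcnj5, Kcnq3, Cacnb1, Cacnb4, Ier2, Fosb, Tsc22d3, H2-T22, Reln, Cplx2, Dnajb1, Hspa1a and Rplp0. Camera then no longer called the lists of calcium channels (adjusted p = 0.444), postsynaptic genes (0.0503), neuropeptides (0.0961), septum and thalamus (0.220) and mural cells (0.0941), and called markers of oligodendrocytes (0.00194) and microglia (8.85e-04) and ribosomal protein genes (0.0063) lower in HDID1. With 6 marker scores as covariates 484 genes passed, 189 higher and 295 lower, and of the 121 named results 52 no longer passed and 8 turned sign. For members of the lists behind the scores such a change is partly built in.

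Vessel lists were called by camera, and lists of glia were not. Among 16 microglial markers Fcrls rose and the receptor genes Cx3cr1 (-0.22, adjusted p = 1.28e-04, 3 of 35 above) and Siglech (-0.29, 5 of 35) fell, 4 adjusted over the list alone. Among 12 astrocyte markers Fgfr3 (0.17, 29 of 35) and Gjb6 (0.32, 22 of 35) rose and the glutamate transporter Slc1a2 (-0.30, 10 of 35) fell, 5 adjusted over the list alone. Camera adjusted p were 0.252 and 0.103, and the microglial median (-0.09) and test lay below 0 and the mean just above it. Of 12 endothelial markers Slco1a4 (-0.25, 8 of 35) and Pecam1 (-0.20, 7 of 35) fell, 5 adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.706 with an estimated correlation). Of 9 mural cell markers Rgs5 (-0.24, adjusted p = 0.00258, 2 of 35) and Abcc9 (-0.45, 7 of 35) fell, 3 adjusted over the list alone (camera adjusted p = 0.0496, adjusted p = 0.706 with an estimated correlation). Scores per library were -0.0802 ± 0.226 in HDID1 and 0.0826 ± 0.253 in HSNpt for endothelial cells and -0.0808 ± 0.195 and 0.0832 ± 0.215 for mural cells (permutation test, two-sided, adjusted p = 0.0232 and 0.00859 over 47 measures). With the 6 marker scores as covariates 0 members of either list passed. The globin Hba-a2 (-1.75, adjusted p = 0.00495, 2 of 35), which has a near-identical copy, fell among 5 blood genes, 2 adjusted over the list alone (camera adjusted p = 0.456). Calb2 (1.01, adjusted p = 0.00938, 27 of 35), the calretinin gene, rose among 12 interneuron markers, 1 adjusted over the list alone (camera adjusted p = 0.621), where the median was below 0 and the mean above it. Calb2 did not pass without the 10 libraries (0.53, adjusted p = 0.203) or with the marker scores (0.0410, adjusted p = 0.931). By either count 0 of 15 oligodendrocyte genes passed (Ugt8a -0.18, adjusted p = 0.218, 9 of 35), 0 of 7 of their precursors (Neu4 0.17, adjusted p = 0.112, 24 of 35) and 0 of 8 of fibroblasts (Col1a2 0.29, adjusted p = 0.0926, 24 of 35). Camera adjusted p were 0.626, 0.718 and 0.264.

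Immune genes were led by the H2 family. Of 13 genes of class I antigen presentation H2-D1, H2-K1 (-0.54, adjusted p = 0.00312, 7 of 35), H2-Q4 (-0.53, 9 of 35) and H2-Q6 fell and H2-T22 (0.30, 29 of 35) and Tap2 rose, 6 adjusted over the list alone (median -0.14, camera adjusted p = 0.0383, adjusted p = 0.733 with an estimated correlation). The toll-like receptor Tlr4 fell from 1.49 ± 0.417 to 1.04 ± 0.310 CPM (-0.54, adjusted p = 4.53e-05, 5 of 35), 1 of 16 and 1 adjusted over the list alone. Of 19 interferon-stimulated genes Xaf1 (-0.45, 10 of 35) fell, 1 adjusted over the list alone. Camera adjusted p were 0.0638 and 0.856. Of 18 matrix genes Hapln1 (-0.28, adjusted p = 0.00199, 7 of 35) and Reln (-0.45, 8 of 35) fell, 6 adjusted over the list alone (camera adjusted p = 0.621, with the median above 0 and the mean below it).

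Of 16 clock genes 5 fell and 0 rose, 7 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 7.65e-05, adjusted p = 0.706 with an estimated correlation). Per2 fell from 38.5 ± 10.2 to 26.8 ± 9.12 CPM (-0.53, adjusted p = 0.00107, 2 of 35 above), and Bhlhe41 (-0.17, 6 of 35), Ciart (-0.27, 4 of 35), Dbp (-0.31, 5 of 35) and Nr1d2 fell with it. Immediate early genes were split. Fos rose to 18.3 ± 5.43 CPM in HDID1 (0.61, adjusted p = 2.86e-05, 33 of 35) with Ier2 (0.34, 25 of 35), while Egr3 (-0.61, adjusted p = 0.0287, 3 of 35) and Fosb (-0.28, 9 of 35) fell, 4 of 17 and 5 adjusted over the list alone (camera adjusted p = 0.493). Of 14 heat shock genes Hspa8 (0.49, 28 of 35), Hspa1a (0.45, 25 of 35; near-identical copies exist) and Dnajb1 (0.21, 27 of 35) rose, 3 adjusted over the list alone (camera adjusted p = 0.148). Of 14 glucocorticoid-responsive genes Tsc22d3 (0.32, 22 of 35) rose, 1 adjusted over the list alone (camera adjusted p = 0.524). Of 75 ribosomal protein genes Rplp0 (0.39, 30 of 35) rose and Rpl34 (-1.54, adjusted p = 2.24e-04, 3 of 35), which has processed copies, fell, 1 adjusted over the list alone (camera adjusted p = 0.0543). By either count 0 of 74 nuclear genes of oxidative phosphorylation passed (Ndufa10 0.18, adjusted p = 0.145, 24 of 35), while camera called the list higher (median 0.14, adjusted p = 0.0383, adjusted p = 0.829 with an estimated correlation), and lower without the 10 libraries that stand apart (adjusted p = 0.00182). By either count 0 of 10 genes of ethanol metabolism passed (Cat 0.11, adjusted p = 0.131, 24 of 35; camera adjusted p = 0.683). Of the Y genes 0 of 4 passed (Kdm5d 1.03, adjusted p = 0.140, 24 of 35), and of 6 X genes that escape inactivation Xist (-3.59, adjusted p = 2.42e-04, 17 of 35) did, 1 adjusted over the list alone. Xist lost its call without the 3 libraries whose X and Y genes go against the label, and camera adjusted p were 0.426 and 0.422. Of the genes named from lists, Slc1a2, Abcc9, Slc18a2, Gnal, Kcnab1, Cacnb1, Cacnb4, Dbp, H2-Q4, H2-T22, Reln, Hspa1a and Xist overlap a gene on the opposite strand, which leaves their values uncertain.

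The line effect was also taken within each sex, with the difference between the sexes as an interaction. In females 130 genes rose and 134 fell, and in males 402 rose and 312 fell, with 125 genes passing in both, 60 higher and 65 lower, all in the same direction. Independent lists would share 3.10 higher and 2.48 lower, a figure that leaves out that genes move together. Of the 1975 genes that passed over both sexes 1974 had the same sign in each, which their choice by the mean of both sexes nearly fixes in advance. Across all genes the log2 fold changes of the sexes had a Pearson r of 0.589 and a Spearman rho of 0.516, where genes are not independent replicates. By edgeR's test 0 genes passed for the interaction, 849 had an unadjusted p under 0.05, and DESeq2 called 1, Xist. The 5 genes of smallest p were Xist (-6.69, adjusted p = 0.160), Gm12346 (0.98), Gm12183 (1.55), Gm1840 (1.02) and Eif4a-ps4 (1.31), with an adjusted p of 0.349 for each of the last 4, which are pseudogenes. Without the 3 libraries whose X and Y genes go against the label the Xist value was 0.74. The female count was 170 without those 3 libraries, and the male count 1265 without the 10 that stand apart.

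Males and females of both lines were compared to see which genes differ by sex. Genes of the sex chromosomes made up most of the difference. Males had RNA of the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty (log2 fold changes of 10.48, 10.41, 10.24 and 10.44), all 4 adjusted over the list alone, and of the Y transcript Gm29650. Xist, the RNA that silences an X chromosome (-6.68, adjusted p = 4.67e-10, 1 of 35 males above the female median; -10.40 without the 3 libraries described next), and the escape genes Eif2s3x (-0.54, adjusted p = 4.68e-14, 1 of 35), Ddx3x (-0.31, 1 of 35), Kdm6a (-0.41, 1 of 35) and Pbdc1 (-0.33, 2 of 35) were lower in males, with the X transcripts 5530601H04Rik and Gm27520, which overlaps Xist (-5.44, and -8.20 without those 3). The escape list thus had 5 of 6 lower, 6 adjusted over the list alone, and Kdm5c was at -0.21 (adjusted p = 0.551). Of 16 genes that passed, 7 higher and 9 lower in males, 4 were autosomal. These were Gm22877 (0.96, 28 of 35 males above the female median) and Greb1 (0.73, 26 of 35), which were higher, and Cdhr1 (-1.07, 9 of 35) and Zfp772 (-0.41, 3 of 35), which were lower. Gm22877 overlaps Slain1.

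In 3 libraries these genes went against the label. The library labelled HSNpt male replicate 10 had 337 CPM of Xist and 0.726 CPM summed over 4 Y genes, and the libraries labelled HSNpt female replicates 14 and 15 had 0.401 and 0.235 CPM of Xist and 0 and 0.0587 CPM of Y genes. Without them 15 genes passed. Greb1 (0.72, adjusted p = 0.0601) and Cdhr1 (-1.08, adjusted p = 0.0691) did not, nor did Gm22877 within HSNpt (1.09, adjusted p = 0.0822), while their log2 fold changes stayed within 0.02 of those with all libraries. The sexes differed in 20 genes within HDID1 and 10 within HSNpt. The HDID1 genes included Slc6a3, which rests on the library named above, Cdhr1 (-1.85), Ntm (-0.22), Jpx (-0.54) and Greb1 (1.08), and the HSNpt genes Dus4l (-0.41) and Gm22877 (1.07), and the difference of these effects between lines is the interaction given above. Among the lists, camera called genes of oxidative phosphorylation (median -0.30, adjusted p = 1.19e-13) and ribosomal proteins (-0.33, adjusted p = 1.19e-13), microglial markers (-0.17, adjusted p = 4.22e-04) and immediate early genes (-0.25, adjusted p = 4.63e-07) lower in males. With an estimated correlation these had adjusted p of 0.867, 0.867, 0.867 and 0.369, 0 of their members passed over all genes, and 6 immediate early genes passed adjusted over the list alone. Without the 10 libraries that stand apart, 6 of them female and 4 male, adjusted p were 6.41e-08, 8.91e-10, 0.00218 and 3.83e-07, lower in males for each. The 5' balance was -0.0431 ± 0.657 in 34 females and 0.0592 ± 0.478 in 35 males, and HDID1 female replicates 6 and 10, at -2.33 and -2.68, had oxidative phosphorylation scores of 1.80 and 1.91 and ribosomal scores of 1.93 and 2.13. Camera called none of the other 37 lists beside those of the X and Y.

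**Figure D3:**
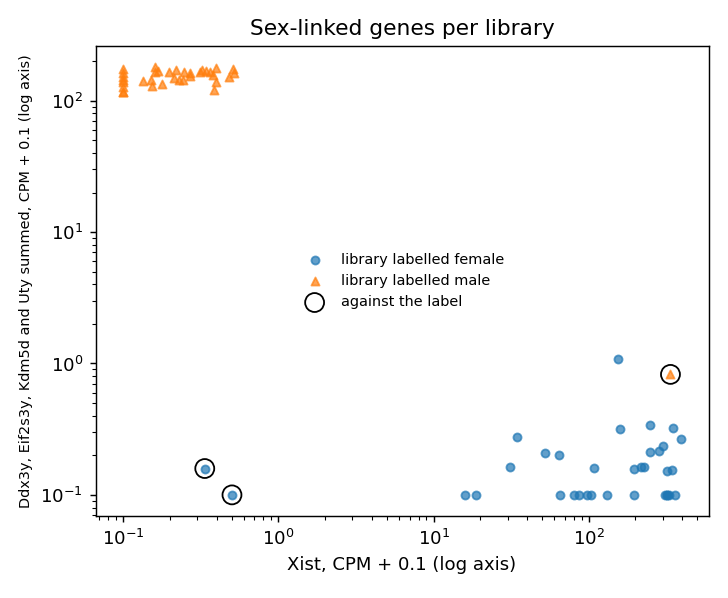
Xist against the sum of Ddx3y, Eif2s3y, Kdm5d and Uty, in CPM with 0.1 added on log axes, 1 point per library by labelled sex. The 3 circled libraries lie apart from the others of their label, 1 labelled male at 337 CPM of Xist and 2 labelled female with under 1 CPM of both.

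Exon usage differed between lines in 533 of 12299 genes, by 593 of 120938 exons, and 76 of these genes were among the 1398 tested genes that also differed in total counts. An exon of Ica1l, a gene related to an islet autoantigen, at chr1 60020791 to 60021384 (exon 4 of 15) had 0 counts in all 35 HDID1 libraries and 0.828 ± 0.704% of the gene's counts in HSNpt. Against 3 counts over the whole HDID1 group it was at least 115-fold lower (Simes adjusted p = 3.63e-69). In Cntfr, the receptor of ciliary neurotrophic factor, the exon at chr4 41695311 to 41695445 held 0.227 ± 0.124% against 1.73 ± 0.855% (relative log2 fold change -2.01, 0 of 35 above the HSNpt median). In Me3, a malic enzyme of mitochondria, the exon at chr7 89818621 to 89818931 held 0.980 ± 0.814% against 0.0951 ± 0.415% (2.99, 26 of 35). The HSNpt mean rested on female replicate 12 at 2.35%, and without it was 0.0267 ± 0.115%, with 28 of 34 HSNpt libraries at 0. Me3 as a whole fell (-0.41). In Rpl21, which has processed copies, the last of 5 exons, at chr5 146835864 to 146837032, held 1.06 ± 0.205% against 13.1 ± 7.72% (-2.57, 0 of 35). In the polyamine enzyme Odc1 the exon at chr12 17550607 to 17551502 held 1.51 ± 0.905% against 4.64 ± 4.35% (-1.14, 6 of 35). HSNpt mice were mixed, so these means do not stand for each mouse. Of 34 HSNpt libraries, 8 lay within the HDID1 range for Rpl21, 19 for Odc1, 8 for Ica1l, 3 for Cntfr and 34 for Me3. For Rpl21 the HSNpt shares ran from 0.719% to 24.3%. An F test per gene in place of Simes called 1657 genes.

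**Figure D4:**
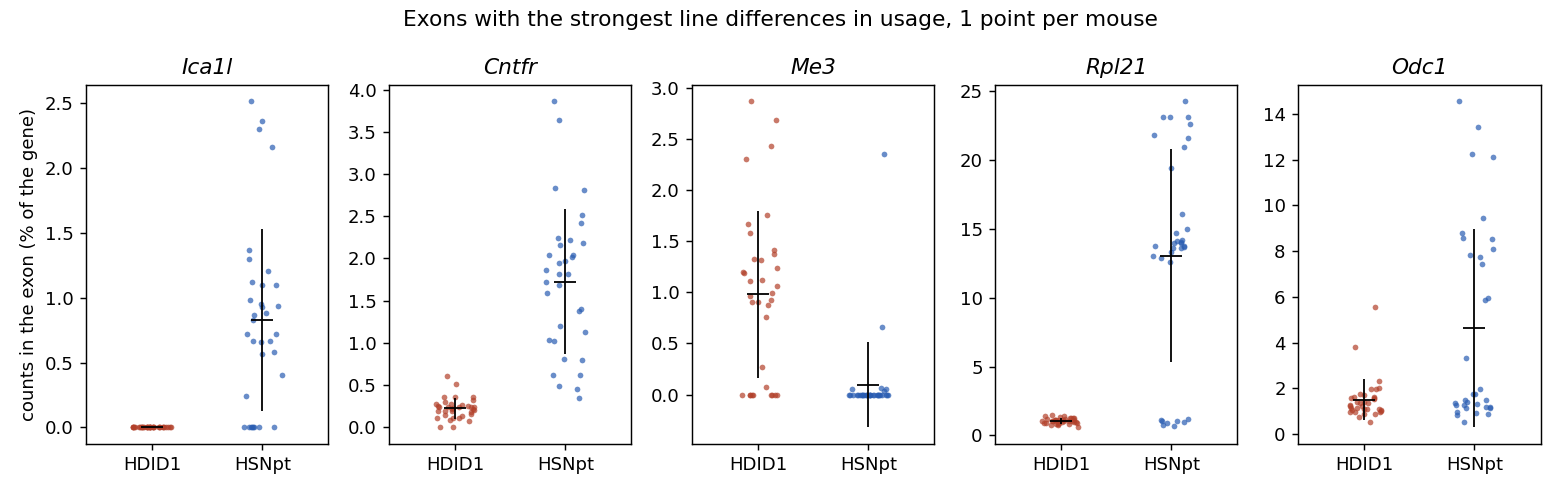
Share of each gene's counts, in percent, that fell in the exon of smallest p in Ica1l, Cntfr, Me3, Rpl21 and Odc1, 1 point per mouse of each line, with mean and SD as black marks. HDID1 libraries hold 0% in the exon of Ica1l, their mean lies below that of HSNpt in Cntfr, Rpl21 and Odc1 and above it in Me3, and the points of the lines overlap in each panel.

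Variability between mice was compared to see whether expression was narrower or wider in HDID1 than in HSNpt. By limma on absolute deviations 8 genes were less variable in HDID1 and 0 more variable, with 593 at an unadjusted p under 0.05. Zfp949, a zinc finger gene, deviated by 0.0973 in log2 CPM from the group median in HDID1 and 0.246 in HSNpt (difference -0.15, adjusted p = 0.0461), and Slc5a5, the sodium iodide symporter, by 0.227 and 0.560 (difference -0.33, adjusted p = 0.0461). Eea1 (-0.46, adjusted p = 0.120) and, on the wider side, 9330151L19Rik (0.42, adjusted p = 0.114) did not pass. Deviations from the group mean gave 62 genes, 21 more and 41 less variable in HDID1, and squared deviations 0. Co-variation of list members differed between lines for 0 of 41 lists, with the lowest p for markers of cortical excitatory neurons, whose mean correlation was 0.414 in HDID1 and 0.641 in HSNpt (permutation test, two-sided, p = 0.0206, adjusted p = 0.444).

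Genes of the line effect lay beside one another along the chromosomes. Neighbours that both passed with the same sign numbered 218, against 115 by permutation of positions (ratio 1.89, p = 1e-05, the smallest these permutations can give). Among genes with an adjusted p under 0.001 there were 20 against 2.24. Leaving out neighbours that overlap or lie within 5 kb gave 103 against 70.7 (ratio 1.46, p = 1.7e-04). The window of 20 tested genes with most members passing, at chr3 96239393 to 96706070, held 12, among them the histone genes Hist2h4 and Hist2h2bb and Polr3gl, Rbm8a and Pias3, 7 higher and 5 lower (p = 0.0028 over all windows). The next, at chr4 6365650 to 11615805, held 11, among them Tox, Car8, Asph and 4930412C18Rik (p = 0.0233). With 6 marker scores as covariates 3 of the 12 genes and 5 of the 11 passed, while neighbouring pairs of the same sign numbered 37 against 7.20. Windows on chr6 at 48626764 to 50596632 with 9 genes, among them Gpnmb and Tmem176b, on chr7 at 97842935 to 99606771 with 9, among them Arrb1 and Wnt11, and on chr11 at 12236608 to 20332713 with 8, among them Meis1 and Cnrip1, were not beyond chance (p = 0.619, 0.619 and 0.993).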

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

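The tests of both wrong sex labels were chosen after the values were seen, as were the settings that add marker scores or the 5' balance as covariates or leave libraries out. The bounds of the other tests were written before their results were seen.

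Blood ethanol is a reading in the file headers that no comparison of expression used. It was 1.38 ± 0.747 in 35 HDID1 mice and 0.516 ± 0.600 in 34 HSNpt mice, in a unit that is not stated, a difference of 0.861 with sex centred (permutation test, two-sided, p = 1e-05, the smallest these permutations can give). Among mice of the same group 0 genes tracked it by edgeR's test, with 288 at an unadjusted p under 0.05, and 0 did within HDID1 (1850), within HSNpt (382) or as a difference of slopes (1995). This argues against tracking strong enough to pass beside the group means. Weaker tracking is not excluded, since recovery of such a slope was not simulated and 16 of 34 HSNpt mice had a reading of 0. Beside blood ethanol 1658 genes passed for line, 1447 of them among the 1975.

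The 1975 genes of the line effect were set against 3 explanations, by values that do not single out the spiny neuron or hypothalamic genes among them. Loss of RNA 5' ends in some libraries is argued against as the whole cause, since with the 5' balance as a covariate the fold changes of the 1975 genes kept a median of 0.874 of their size (quartiles 0.751 and 0.992) and 1581 of them still passed. Tissue bordering the ventral striatum stays open, because with 6 marker scores as covariates that median was 0.578 (quartiles 0.327 and 0.843) and 378 of 1966 genes outside the lists still passed, which met neither bound written in advance. A difference between the lines in the cells themselves also stays open, untested, and 2 of the 9 hypothalamic genes tested are in another list. In HDID1 female replicate 5, Slc6a3 at 97.3 CPM and a spiny neuron score of -3.18 may come from tissue outside the striatum. The 20 genes named by rule, which had to pass in each sex, also passed with the scores as covariates, 5 of them with folds over 1.5 times smaller. They need not stand for all large differences. Outside that rule Oxt and Slc6a3 turned sign with the scores. Oxt is itself a hypothalamic marker, and Slc6a3 rested on HDID1 female replicate 5, so these sign changes say little about other genes.

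The 218 neighbouring pairs of the same sign were set against shared reads and strain variants. Reads shared by overlapping neighbours stay open. When pairs that overlap or lie within 5 kb were left out, 103 remained against 70.7 by permutation (SD 8.16, p = 1.7e-04). The highest permutation reached 111, and the bound written in advance took a count no higher than that as the outcome of shared reads. The permutation p, which was not that bound, points to an excess among pairs farther apart. The test therefore decides neither way, and a part of the excess may still come from shared reads. Variants of the founder strains against the reference stay open. The paired genes had an exon call 1.08 times as often as other genes of the line effect (95% interval 0.635 to 1.85), but the bound written in advance was wrong, because variants could affect those other genes alike and chance is not excluded for the exon calls. A hypothesis that was not tested is that alleles fixed by breeding in stretches of chromosome carry neighbouring genes together.

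For the 3 libraries whose X and Y genes go against the label, a wrong sex label fits the library labelled HSNpt male replicate 10, with 0.726 CPM of 4 Y genes where other males had 116 to 179, and 337 CPM of Xist where other females had 15.7 to 391. The libraries labelled HSNpt female replicates 14 and 15 are argued against as males by at most 0.0587 CPM of Y genes. A single X chromosome in them would lower genes that escape inactivation, whose mean log2 CPM was 6.06 and 5.74, inside the range of other females. The bound written in advance was wrong, because males (5.19 to 6.15) and females (from 5.33) overlap, so 1 X chromosome cannot be told apart from 2 by this value. No other biological explanation was tested.

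Chance was examined with other splits of the same libraries, 100 for each count except 30 for exon usage. The splits shuffled single mice, so they cover the sampling of mice and say nothing about selection. Mice that share a lab number lay within 1 group, and the splits did not keep them together. Chance assignment of mice is argued against for the line effect, since 1 split, the real one, gave as many genes (1975, highest other 1694), and in males (1 of 100, 714, highest other 3). In females 5 of 100 splits gave as many (264, highest other 2386), so the splits do not exclude chance, while 125 of the 264 genes also passed in males, which are other mice, all with the same sign, where independent lists would share 3.10 higher and 2.48 lower. Genes move together across these libraries, so the expectation for independent lists does not hold here. The overlap therefore does not decide whether chance lies behind the 264. For exon usage chance cannot be excluded (2 of 30, 533 genes, highest other 549). For the interaction the real count was 0, so all 100 splits gave as many whatever they held (100 of 100, highest other 2795), which says nothing about chance. Few splits gave as many for sex (4 of 100, 16 genes, highest other 3316), sex in HDID1 (3 of 100, 20, highest other 2329), sex in HSNpt (2 of 100, 10, highest other 35) and variability (4 of 100, 8, highest other 2728). No adjustment was made over these counts. The sex count holds 5 Y and 7 X genes, that within HDID1 5 and 5, and that within HSNpt 5 and 3. Shuffled labels part such genes from sex, so a low number of these splits was largely fixed in advance. The splits do not bear on the 4, 10 and 2 autosomal genes of these counts. The variability count was 0 with squared deviations and 2 with a stricter filter, so chance is not excluded for it. Splits that call several times the real count, as in females, for sex and for variability, point to a structure of the samples other than their groups, as does the split with 2795 genes for the interaction.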

How the results depend on the processing

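Settings that leave out libraries, or add marker scores, the 5' balance or the lab number, were chosen after seeing the data. Of the counts, the line effect stayed within 1.5 times of 1975 in 11 of 15 alternatives, over a range of 151 to 3902, and the 121 named results kept direction and side of the threshold in 121 cases with RLE scaling, 118 with DESeq2 and 61 with the marker scores. Causes were not tested except where the construction shows them. With voom and quality weights the counts were 3902 for line, 561 in females, 3988 in males, 110 for sex and 1193 for sex in HDID1, and the line value of Xist turned to 0.11. DESeq2 gave 409 in females, 1 for the interaction and 34 for sex in HDID1. A test against a fold change of 1.2, which asks for more by construction, gave 151. With surrogate variables sex gave 29 and Enkur turned to -0.00580. With only the groups compared, which leaves fewer libraries, there were 82 in females, 1079 in males and 6 for sex in HSNpt.

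Without the libraries standing apart the counts were 1226 for line, 1265 in males, 28 for sex, 20 for variability and 14 lists for sex, and Ndufa10 turned to -0.00182. Without the 3 libraries whose X and Y genes go against the label females gave 170 and the interaction of Xist turned to 0.74. Without the libraries with the highest totals the interaction gave 1 and sex in HSNpt 6. With the 6 marker scores there were 484 for line, 159 in males, 16 for sex in HSNpt and 5 lists for line, and Drd2 turned to 0.00808, Enkur to -0.13, Gal to -0.0550, Oxt to -0.29, Grik1 to -0.0703, Slc6a3 to -0.10, Oprl1 to -0.0129 and Pnoc to -0.10. With the 5' balance there were 501 in females, 1738 in males, 2 for the interaction and 34 for sex in HDID1. With voom and the lab number as a random block, 2 changes at once that were not run apart, females gave 168 and sex in HDID1 13. An F test gave 1657 genes for exon usage. Variability gave 62 from the group mean, 0 with squared deviations, 2 with a stricter filter and 32 on surrogate variable residuals. With an estimated correlation 0 lists were called for line and 2 for sex, and fry called 7 and 2. The lowest total of 14077983 limits genes near the floor of 0.213 CPM, and simulated changes of 1.2-fold were recovered for 34% of genes.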

Other observations

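The families below were chosen after the line effect had been seen, and no test of this part was set before that. In the protocadherin beta cluster at chr18 37264938 to 37507822, whose genes encode adhesion molecules of neurons, 4 of 20 genes were lower in HDID1 and 1 higher. Beside Pcdhb6 and Pcdhb7 these were Pcdhb5 (-0.30, adjusted p = 0.00863, 4 of 35 above the HSNpt median) and Pcdhb4 (-0.35, adjusted p = 0.0123, 6 of 35), and Pcdhb9 was higher (0.39, adjusted p = 7.40e-04, 33 of 35). In the gamma cluster at chr18 37661793 to 37818555, 4 of 14 genes were lower and 0 higher, Pcdhgb6, Pcdhgb2 (-0.54, 2 of 35), Pcdhgb8 (-0.61, 1 of 35) and Pcdhgb5 (-0.51, 2 of 35). Of 4 alpha genes tested 0 passed by edgeR's test. With 6 marker scores as covariates 2 beta genes and 1 gamma gene passed, and the medians went from -0.06 to 0.03 and from -0.19 to -0.11, while 6 and 7 passed without the 10 libraries that stand apart. RLE scaling turned the sign of Pcdhb13 and Pcdhgb1, both within 0.01 of 0, and of no other member. Near-identical copies leave these values uncertain.

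Of 12 replication-dependent histone genes, whose transcripts mostly lack a poly-A tail, 3 were lower in HDID1 and 1 higher, with no sign turned by RLE scaling, and 3 passed with the marker scores. Hist1h2al (-2.41, adjusted p = 8.01e-06, 0 of 35 above), Hist2h2bb (-1.67, adjusted p = 1.46e-09, 1 of 35) and Hist2h4 (-0.92, adjusted p = 4.95e-04, 4 of 35) were lower and Hist2h2be was higher (0.47, adjusted p = 1.16e-06, 33 of 35). Their counts were low, with means over all libraries of 1.42, 0.710, 0.815 and 4.99 CPM in that order, below the 5 CPM of the naming rule. Hist2h2bb and Hist2h4 lie in the window of chr3 that held the most genes of the line effect.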
